A study of Mus musculus with 15 samples.

How the data were processed

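The study measured RNA of whole pancreas from 15 C57BL/6 mice aged 7 months by sequencing. Per the labels, 3 wild-type animals formed the group Normal, and animals of a Kras overexpression genotype formed the groups All (6), Alcohol (3) and Control (3). The labels do not explain the name All. Total RNA was extracted with an RNeasy kit and all libraries were built with a TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name STAR and Partek. Their versions, the genome build and the annotation are not given in the sources used here.

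The values came from the authors' deposited table of 21249 genes, which holds no value per library. The table gives the authors' mean RPKM of each group, computed with 1 read added per gene and library, and RPKM summed over libraries and in the highest library. It also gives, per the file headers, the ratio and signed fold of the group means for 6 comparisons of the 4 groups. A p-value and a step-up FDR of each comparison are deposited beside them, from a model that the headers do not name. Checks on the table showed that the sum equalled group sizes times group means (largest relative gap 2.93e-13). The deposited ratio equalled the quotient of the authors' means within a relative tolerance of 1e-06 for 21249 genes, and the deposited FDR equalled a Benjamini-Hochberg adjustment over all genes (largest gap 1.83e-14). In 22 cases a gene name had turned into a date. By symbol, chromosome and start, 20998 genes matched the GENCODE M21 annotation (GRCm38), and 20938 of these also matched by end, so coordinates are printed on that annotation.

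Depth was read from the genes without reads, whose RPKM times exonic length is a constant set by the added read (relative tolerance 0.005). The constant gives a harmonic mean of 12.7 M reads per library in Normal, 38.2 in Control, 38.2 in Alcohol and 12.0 in All. The share of matched genes with fewer than 1 read per library on average was 30.1% in Normal, 20.7% in Control, 14.0% in Alcohol and 14.5% in All. Where the lower group held 3 reads or fewer, group means are given in place of a fold, except for Gzmb where its sign changed with the scaling.

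The tests planned before the data were examined needed values per library and could not be run, so the test reported for each comparison is the authors' own, at an FDR under 0.05. The authors' p-values of a gene fit a model of 4 group means on 15 libraries with 15.01 degrees of freedom, 11 of them residual. From the 6 p-values and the 6 deposited log2 ratios, the t values and the residual error of each gene were recovered for 20314 genes. The other 935 genes were left out of what follows, because the agreement of log ratios and recovered differences was under 0.95 (cosine) or the root mean square log2 ratio was under 0.5. Both limits were set after counts without them had been seen. The median residual SD was 0.56 (log2). Since the median gene of most comparisons lay far from 0 on the deposited scale, each gene was also tested against the median log2 ratio of its comparison, with a Benjamini-Hochberg adjustment. Below, this is the test about the median gene, and "rose" and "fell" refer to it unless the deposited scale is named. It treats the median as known. It stands for the rescaling by median ratio that had been planned as an alternative, and it is not the main test. The added read pulls log2 ratios of genes with few reads toward 0. About a median above 0, such genes therefore lean lower in this test.

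The recovery and this test were tested on simulated data for All versus Normal, with 200 of 20314 genes changed. It called 123 genes, of which 7 were unchanged, and found 4% of changes of 1 log2, 46% of 2, 84% of 3 and 98% of 4. With variation shared by libraries it called 100 genes, of which 4 were unchanged, and found 0% of changes of 1 log2 and 22% of 2. No changed gene was called with the wrong sign. The simulated changes had random signs, and each gene had the same error in all groups. The simulation therefore cannot show that the median is the right reference in the data, where 5454 genes passed about it. It also drew normal errors on log2 values, without read counts or an added read. Only genes whose real error had been recovered within the limits were simulated. How the recovery and test behave for genes with few reads was therefore not tested.

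Before the data were examined, 45 gene lists were fixed. Each list was tested with camera (cameraPR of limma 3.58.1, two-sided, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison) on the recovered t values of the deposited scale, which is the main list test. The same test on t values about the median gene was planned as a change of scaling. A correlation of 0.05 and a test on ranks were added after the data were seen, because a correlation cannot be estimated without values per library. Where genes of a list move together more than the preset correlation allows, their list p-values are too small. The lists described below were picked, out of the 45, after their values had been seen, and so were the lists drawn in the plot of lists. In the texts, a list adjusted p is from the main list test unless it is said to be about the median gene.

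Named genes followed a rule written before the data were examined. Kras comes first in each comparison. Then come the 10 genes with the largest rise and the 10 with the largest fall among those past the authors' threshold with at least 5 RPKM in the higher group, without predicted genes and antigen receptor segments. Last come up to 4 members of each list described with the smallest p-value, or 2 where none passed. The rule's condition that samples of both groups do not overlap could not be applied. Genes named outside the rule were chosen after their values were seen. They are the exceptions within a list count, the genes past any of the tests in Alcohol versus Control, the sex-linked genes, the structural RNAs and histones outside the largest changes, and the genes read from the highest library.

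A gene was taken as held by 1 library when the table's maximum could lie in only 1 group and made up at least 80% of that group's sum. The table does not say which library of the group it was, or whether it was the same library for each gene. Small sets of stomach, lung, clock, immediate early and heat shock genes were written after these patterns had been noticed. The minimum of 0.1 RPKM in the counts of parietal and duct genes was added after 6 of 10 parietal genes had been counted without it, and 4 remained.

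Alternatives recomputed from the table were the median-ratio rescaling, a scaling on reads outside the acinar enzymes, a mean of at least 10 RPKM, and a test against an absolute log2 difference of 1. A mean of at least 1 RPKM, the test about the median gene over all genes, and the RAS and ERK list without Egr1 and Fos were added after the data were seen. Other alternatives in the plan needed values per library and were left out. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.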

Results

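RNA of pancreas was compared between wild-type mice (Normal, 3 animals) and mice with a Kras overexpression genotype, in the groups All (6), Alcohol (3) and Control (3). Kras encodes a small GTPase whose activation drives pancreatic tumours in mice. The series is titled as a study of pancreatic cancer tissue. Libraries of Normal and All held about 12.7 and 12.0 M reads (harmonic means), and those of Control and Alcohol held 38.2 M each.

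Small noncoding RNAs that help to export proteins, mature transfer RNA and process ribosomal RNA separated the groups into pairs that cut across genotype. Rn7s2, a signal recognition particle RNA, had an authors' mean of 276368 RPKM in Normal and 135361 in All, against 11.8 in Control and 32.2 in Alcohol. Rn7sk, Rpph1 and Rmrp, whose products act in transcription and RNA processing, were likewise high in Normal and All and low in Control and Alcohol. Histone genes whose messages end without a poly(A) tail followed the same split. Among 63 of them, the median log2 ratio of Control to Normal was -4.18, while that of All to Normal was 2.05. Xist, which silences an X chromosome in females, averaged 20.7 RPKM in Normal and 67.5 in All, against 0.00394 in Control and 0.00638 in Alcohol. The Y-linked gene Ddx3y, which encodes a helicase, averaged 0.00403 RPKM in Normal and 0.00647 in All, against 0.780 in Control and 1.06 in Alcohol. The 154 small and structural RNAs took 52.7% of the reads on listed genes in Normal and 47.7% in All, but 0.614% in Control and 1.57% in Alcohol. Comparisons of Normal or All with Control or Alcohol therefore cannot be told apart from this split. All versus Normal and Alcohol versus Control lie within its sides and are given first.

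**Figure D1:**
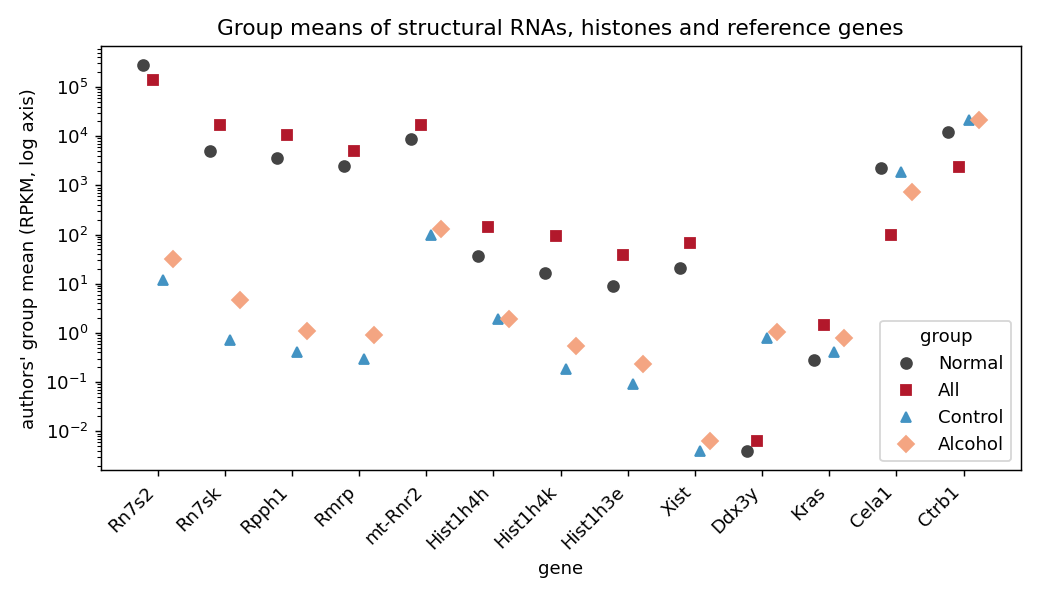
Authors' group means (RPKM, log axis) of 13 genes, with 1 symbol per group and no error since the table holds none. Rn7s2, Rn7sk, Rpph1, Rmrp, the histone genes and Xist lie high in Normal and All, and Ddx3y lies high in Control and Alcohol.

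All versus Normal asks how pancreas of the Kras genotype differs from wild-type pancreas. Kras itself (chromosome 6, 145216699 to 145250239) had an authors' mean of 1.42 RPKM in All and 0.283 in Normal. Digestive enzymes of acinar cells, the cells that make pancreatic juice, fell. Cela1, an elastase, dropped from an authors' mean of 2216 RPKM to 95.6, and Zg16, a protein of secretory granules, from 116 to 6.71. Pla2g1b, a secreted phospholipase, and the trypsinogen Try10 fell as well. In the authors' deposited table, Kras had a log2 ratio of 2.32 with an FDR of 2.97e-05, and 17691 of 21249 genes passed, 17179 higher and 512 lower in All. The median gene lay at a log2 ratio of 2.01, and about it 5454 genes passed, of which 2738 rose and 2716 fell. Reads outside the acinar enzymes and the structural RNAs had a log2 ratio of 1.82 at equal depth. Much of the rise on the deposited scale thus went with read composition. Relative to the median gene Kras lay at 0.32 and did not pass (adjusted p 0.541).

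Enzymes, granule proteins and the factors that build the secretory apparatus went together. Of 30 acinar enzymes, 28 were lower and 1, the trypsinogen Prss1, was higher in the authors' deposited table, the same as when adjusted over the list alone. Prss3 did not pass. Against the median gene, 28 fell and none rose, by a median of -5.48. Bhlha15, which directs the maturation of the secretory granules, and Tmed6, a cargo receptor, fell, by -4.40 and -5.16. Of 19 secretory and acinar transcription genes, 14 fell about the median gene, and the transcription factors Gata6 and Prox1, which passed as higher on the deposited scale, did not (0.07 and 0.44). As lists, the enzymes had an adjusted p of 1.93e-42 and the secretory genes 7.77e-13. Acinar enzymes took 33.4% of the reads on listed genes in Normal and 3.49% in All.

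Among the 10 largest falls were also Gal, which encodes a neuropeptide, and Fgf21, a hormone that acinar cells secrete. Gal averaged 5.03 RPKM in Normal and 0.110 in All, and Fgf21 6.94 and 0.373. The pseudogenes Fth-ps3, Rpl9-ps8, Rpl28-ps3, Rps12-ps10 and S100a11-ps made up 5 of the 10. Reads of such pseudogenes can be shared with the parent genes, which was not tested, and their changes are uncertain.

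Genes of the stomach's mucous lining, which are also switched on in early pancreatic lesions, rose from near absence. Gkn1 and Gkn3, secreted proteins of gastric mucus, averaged 81.0 and 74.4 RPKM in All, and Tff1, a mucus peptide, averaged 89.4, where Normal had at most 0.230. Gcnt3, which builds mucin sugars, the tight junction gene Cldn2, the protease gene Ctse, the mucin gene Muc5ac, and Gkn2 were among the 10 largest rises too, with the hormone gene Ghrl and the iron-binding neutrophil and epithelial protein gene Ltf. In 5 of the 10, Normal held 3 reads or fewer. Of 27 gastric-type genes, 22 passed as higher in the authors' deposited table and also when adjusted over the list alone. In the test about the median gene 17 rose, with Muc4 and Onecut3 among them, and only Dmbt1 fell. The list median was 5.28 relative to the median gene (list adjusted p 6.88e-05 on the deposited scale and 7.53e-14 about the median gene).

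Duct and tuft cell genes rose as well. Onecut2 and Sox9, transcription factors of ducts, rose by 6.28 and 1.83, and Cldn4, a tight junction protein, by 3.76 relative to the median gene. Cftr, the chloride channel of ducts, averaged 1.14 RPKM in All and 0.0106 in Normal. Tuft cells are chemosensory cells that appear in injured pancreas, and their genes Avil, Siglecf and Alox5 rose from 3 or fewer reads in Normal, while Dclk1 rose by 3.97. All 26 duct genes and all 12 tuft genes passed as higher in the authors' deposited table, over all genes and when adjusted over the list alone. Against the median gene, 21 duct genes rose and Onecut1 fell, and 10 tuft genes rose. Adjusted list p values were 3.29e-11 for ducts and 6.36e-06 for tuft cells.

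Genes of connective tissue and its remodelling rose. Col5a1 and Col6a1, collagen chains, rose by 3.30 and 2.32 relative to the median gene, the cross-linking enzyme gene Loxl1 by 2.74 and the microfibril gene Fbn1 by 2.75. The matrix proteases Mmp23, Adamts1, Adamts2 and Adamts5 rose, and so did the fibroblast genes Pi16, Rbp1 and Gli1, with Pdpn averaging 2.90 RPKM against 0.0725. All 32 matrix genes and all 29 protease genes passed as higher in the authors' deposited table and when adjusted over the list alone, and 30 and 21 of them rose about the median gene. Of 28 fibroblast and stellate genes 25 passed, also adjusted over the list alone, and 12 rose. Adjusted list p values were 1.35e-11 for matrix and 0.000208 for proteases. For the fibroblast list it was 0.0996, and 2.41e-05 about the median gene.

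Macrophage genes rose, while of the lymphocyte genes tested about the median gene only Sdc1 did. Cd14, a receptor for bacterial products, averaged 40.1 RPKM in All and 0.792 in Normal. Mrc1, Trem2 and Ccr2, receptors of tissue macrophages and of recruited monocytes, rose by 2.41, 3.41 and 2.75 relative to the median gene. The cytokine gene Ccl9 rose by 3.26, and Il1a, Lif and Cxcl5 rose from 3 or fewer reads. The neutrophil genes Ltf, Csf3r and S100a9 rose and Il1r2 did not pass (adjusted p 0.0762). For S100a9, 1 All library held 85.2% of the group's sum, at 39.6 RPKM where the others averaged 1.37, and 1 library likewise held at least 80% for 7 of the 15 neutrophil genes. T cell genes such as Pdcd1, Foxp3, Gzmb and Il2ra, and the B cell genes Tnfrsf13b and Jchain, did not pass about the median gene, while Sdc1, which epithelium also makes, rose. Normal held 0.62 reads of Pdcd1, 3.60 of Foxp3, 0 of Gzmb and 6.40 of Il2ra, but 549 of Jchain, and Trem2 rose from 4.58. The added read pulls such low genes below the median gene, so their contrast with macrophage genes may reflect few reads. Only 20 of the 25 T and NK cell genes were tested about the median gene. All 24 macrophage genes passed as higher in the authors' deposited table and adjusted over the list alone, and 19 rose. For T and NK cells 12 of 25 passed (5 adjusted over the list alone) and for B and plasma cells 6 of 23 (3 adjusted over the list alone), against 0 and 1 about the median gene. Macrophages had a list adjusted p of 0.000759. It was 0.000174 for T cells and 1.65e-06 for B cells, both toward lower t values than other genes, and 0.700 and 0.827 about the median gene. Of 30 cytokine genes 27 passed, the same number adjusted over the list alone, and 17 rose (list adjusted p 0.213, and 1.48e-06 about the median gene). Of 15 neutrophil genes 11 passed, also adjusted over the list alone, and 3 rose about the median gene. The list test leaned to lower t values (adjusted p 0.213) although the list median lay 2.36 above the median gene.

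Genes of growth factor signalling rose. Hbegf and Btc, ligands of the EGF receptor family, and the receptors Erbb2 and Erbb3 rose, with Erbb3 at 1.79 and Hbegf at 4.33 relative to the median gene, whereas Egf fell by -4.36. Targets of RAS and ERK rose too. These included Dusp4, a phosphatase that limits ERK, at 2.55, and the transcription factors Etv1 at 2.18 and Elf3 at 2.85, while Spry1 did not pass (adjusted p 0.0565). Ccn2, Tgfb3, Pmepa1 and Inhba, which TGF-beta signalling induces or which signal through its pathway, rose by 3.51, 2.99, 4.08 and 3.61. In hedgehog and WNT signalling Gli1, Smo and Wnt5a rose, and Gli2 rose from near 0 reads. Of the fixed lists in the authors' deposited table, 25 of 26 RAS and ERK genes, 21 of 21 TGF-beta genes and 29 of 32 NOTCH, WNT and hedgehog genes passed as higher, each also when adjusted over the list alone. Of these, 18, 12 and 19 rose. Of 12 EGF receptor family genes 11 passed as higher and 1 as lower, also adjusted over the list alone, and 6 rose and 1 fell about the median gene. The list adjusted p values were 1.65e-06 for RAS and ERK, 6.41e-05 for TGF-beta, 0.00174 for NOTCH, WNT and hedgehog, and 0.0342 for the EGF receptor family, which reached 0.0887 with a correlation of 0.05.

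Protein production genes fell behind other genes. Phgdh, the entry enzyme of serine synthesis, fell by -3.79 relative to the median gene. Calr and Canx, chaperones of the endoplasmic reticulum, and the stress genes Ppp1r15a and Atf3 passed as higher on the deposited scale and did not pass about the median gene. Gls, Got2 and Slc1a5, which handle glutamine and aspartate, and the ribosomal genes Rpl14, Rpl18, Rps5 and Rps19 behaved likewise. Of 26 unfolded protein response genes 15 were higher and 6 lower in the authors' deposited table, and of 23 amino acid genes 12 and 10, the same when adjusted over the list alone. About the median gene 13 and 12 fell and none rose. All 35 ribosomal protein genes passed as higher, also adjusted over the list alone, but 23 fell about the median gene (list adjusted p 0.792, and 2.32e-09 about the median gene). The list adjusted p was 0.000745 for the unfolded protein response and 3.68e-08 for amino acids.

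Injury genes split, and no proliferation gene passed about the median gene. Lcn2, which binds bacterial iron carriers, and Clu, a secreted chaperone of damaged epithelium, rose by 6.43 and 1.99 relative to the median gene, with Anxa1 and Anxa2. Reg1, Reg3d, Spink1 and Nupr1, which acinar cells make, fell. The DNA replication genes Mcm4, Mcm7 and Tyms and the spindle gene Bub1b did not pass about the median gene. Among islet genes Ppy, Pyy and Mafb rose with Ghrl. Of 20 injury genes 14 passed as higher and 4 as lower in the authors' deposited table and adjusted over the list alone, and 8 rose and 4 fell about the median gene. The injury list test leaned to lower t values (adjusted p 0.276) although its median lay 1.71 above the median gene. Of 32 cell cycle genes 31 passed on the deposited scale, also adjusted over the list alone. None passed about the median gene in the recovered limma-type test, where 7504 genes had an unadjusted p under 0.05. The cell cycle list leaned to lower t values (list adjusted p 0.321, 0.248 about the median gene and 0.0367 on ranks). Of 24 islet genes 13 passed (12 adjusted over the list alone), and 5 rose and 4 fell about the median gene (list adjusted p 0.464 on the deposited scale and 0.815 about the median gene).

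**Figure D2:**
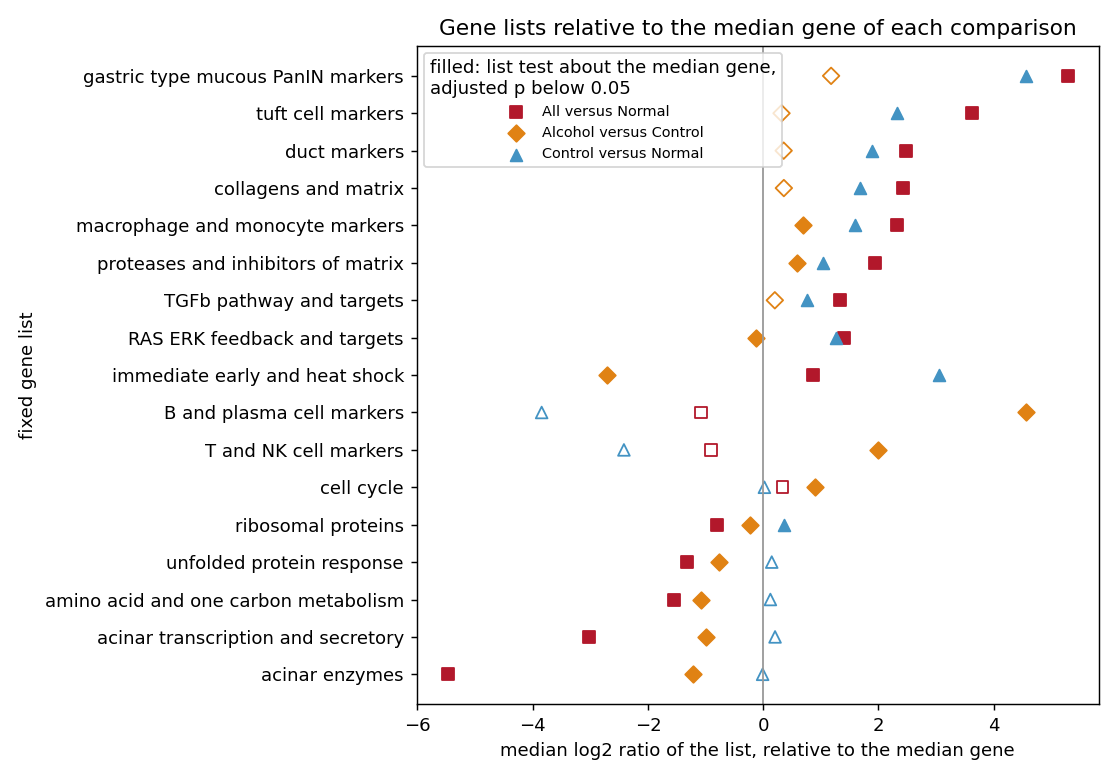
Median log2 ratio of fixed gene lists relative to the median gene of the comparison (horizontal axis), for All versus Normal, Alcohol versus Control and Control versus Normal, with filled symbols where the list test about the median gene passed. Acinar enzymes lie at -5.48 in All versus Normal, and immediate early and heat shock genes at -2.71 in Alcohol versus Control.

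Alcohol versus Control compares Kras genotype animals by the word alcohol in their group name. Kras averaged 0.794 RPKM in Alcohol and 0.403 in Control. Egr1 (chromosome 18, 34859823 to 34864984), a transcription factor switched on within minutes of stimulation, fell from an authors' mean of 82.1 RPKM to 2.99. Immediate early genes and heat shock genes fell as a group. Fosb, Zfp36, Egr2 and Dusp1 fell along with Egr1 about the median gene. Tdh, which breaks down threonine, fell from 0.195 to 0.0124 RPKM. By the FDR in the authors' deposited table, 17 genes passed, 15 higher and 2 lower, where 9451 had an unadjusted p under 0.05 and 8113 an FDR under 0.1. Egr1 had a log2 ratio of -4.78 with an FDR of 0.0271 in the authors' deposited table, and Kras 0.98 with an FDR of 0.126. The median gene lay at 0.93, and about it 25 genes of those with a recovered error within the limits passed, which all fell. Without these limits, which were set after counts without them had been seen, 53 genes passed over all genes, 52 lower and 1, the long noncoding RNA Gm9913, higher (adjusted p 0.0441, and 0.0509 with the limits). Within the limits 2 genes, Egr1 and Tdh, passed both ways, and none of the 15 deposited rises passed about the median gene, where 1693 genes had an unadjusted p under 0.05 by the recovered limma-type test.

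The immediate early and heat shock list had the lowest median. Of its 18 genes 1 passed in the authors' deposited table and 12 when adjusted over the list alone. About the median gene these were 5 and 18. The list adjusted p was 5.42e-58 on the deposited scale and 1.55e-43 about the median gene. Against Normal, across the split, this list lay at 3.05 in Control and 0.81 in Alcohol, relative to the median gene. Nr1d1, a repressor in the circadian clock, averaged 4.72 RPKM in Alcohol and 0.869 in Control. It passed in the authors' deposited table with an FDR of 0.0465. It did not pass about the median gene (adjusted p 0.234), and the clock list did not (1 of 18 on the deposited scale and 7 adjusted over the list alone, against 3 higher and 1 lower so adjusted about the median gene, with a list adjusted p of 0.710 on the deposited scale and 0.472 about the median gene).

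Genes of B cells, which make antibodies, were listed far higher in Alcohol without passing singly. Cd19 averaged 2.54 RPKM in Alcohol and 0.0152 in Control, and Ms4a1 0.879 and 0.00688. The T cell gene Cd8b1 and the killer cell gene Gzma, and the neutrophil genes Ltf and Ngp, leaned the same way. Interferon-induced genes such as Ifit2 and Ifit3 did so by less. In the authors' deposited table none of the 23 B cell, 25 T cell, 15 neutrophil and 32 interferon genes passed, and adjusted over the list alone 23, 15, 7 and 20 did. These calls are on the deposited scale, and about the median gene, which lay at 0.93, they were 14, 0, 2 and 0. The list adjusted p was 1.19e-06 for B cells, 0.0492 for T cells and 0.00133 for interferon. The neutrophil list had 0.176, and 6.35e-07 about the median gene. At a correlation of 0.05 the B cell and interferon lists held (0.000639 and 0.0450) and the T cell list did not (0.200). For B cells, Control rather than Alcohol lay apart from Normal, where Ms4a1 averaged 0.776 RPKM. Relative to the median gene, the B cell list lay at 0.50 in Alcohol versus Normal and -3.84 in Control versus Normal. It passed in neither (list adjusted p 0.970 and 0.107), and both cross the split. Whether 1 Alcohol animal carried the B cell genes cannot be told without values per library. The rule for 1 library needs a maximum above the sum of every other group, and Normal held these genes at similar levels.

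Acinar enzymes leaned lower, with a list median of -0.29 on the deposited scale and -1.22 relative to the median gene. Amy2a5, an amylase, averaged 55.1 RPKM in Alcohol and 1914 in Control. Its near-identical copies can share reads, which was not tested, and its value is uncertain. Pla2g1b averaged 42.8 and 110. Unfolded protein response genes had a median of 0.17 on the deposited scale and lay lower only relative to the median gene (-0.77), where the chaperone genes Canx and Pdia4 were at -0.23 and 0.06. The oxidative enzyme genes Cat and Adh5 were at 0.24 and 0.13 on that scale, and the gastric genes Gkn3 and Vsig2 at 1.45 and 1.16. In the authors' deposited table no gene of the acinar, gastric, unfolded protein response or alcohol metabolism lists passed. Adjusted over the list alone 7 of 21 alcohol metabolism genes passed as higher on the deposited scale, and none of the others. So adjusted about the median gene, 0 alcohol metabolism genes were higher and 1 lower, 14 unfolded protein response genes were lower, and no acinar or gastric gene passed. The list adjusted p was 7.10e-19 for acinar enzymes, 1.09e-05 for the unfolded protein response and 0.683 for alcohol metabolism. About the median gene these were 3.22e-05, 5.44e-13 and 0.584. At a correlation of 0.05 the acinar list had 5.00e-10. The true correlation of the enzymes is unknown, so the size of these p-values is uncertain.

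Control versus Normal compares the Kras genotype with wild type across the split in structural RNA. Kras averaged 0.403 RPKM in Control and 0.283 in Normal. Reg3a, Reg3b and Reg3g, antibacterial proteins of inflamed pancreas, rose, with Reg3b at 716 against 12.5 RPKM. The heat shock chaperones Hspa1a and Hspa1b and the immediate early genes Egr1, Junb and Zfp36 rose, and so did the gastric genes Gkn1, Gkn3 and Tff1. Gkn2, Muc4, Ctse and Agr2 rose from 3 or fewer reads. Duct genes rose too, with Muc1 at 1.96 and Cldn4 at 3.98 relative to the median gene, and Krt20 and Tspan8 from 0 reads. The matrix genes Thbs1, Fbn1 and Fn1 rose, with Col8a1 and the chemokine gene Ccl2. The B cell genes Ms4a1 and Fcmr fell and Sdc1 rose. The largest falls were Rn7s1, Rn7s2, Rn7sk, Rpph1, Rmrp, Mir6236, Scarna2, Xist, Glycam1 and Amy2a1, an amylase with near-identical copies, and Rpl17-ps5 and Rps23-ps2 among the largest rises are pseudogenes. The authors' deposited table had 5653 genes passing, 3044 higher and 2609 lower, and Kras had an FDR of 0.413. About the median gene (0.14) 2369 rose and 2880 fell.

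All 18 immediate early and heat shock genes passed as higher in the authors' deposited table, 21 of 27 gastric, 21 of 26 duct, 12 of 20 injury and 21 of 32 matrix genes. Adjusted over the list alone these were 18, 21, 24, 14 and 26, and 18, 19, 20, 12 and 18 rose about the median gene. In that order, the list adjusted p values were 2.21e-10, 2.52e-09, 4.30e-09, 3.90e-05 and 3.90e-05. Of 23 B cell genes 1 was higher and 2 lower, with 0 adjusted over the list alone (list adjusted p 0.107). The acinar enzymes took 33.4% of reads on listed genes in Normal and 70.3% in Control, where structural RNAs took 52.7% and 0.614%. These shares therefore follow the split and do not show a rise of the enzymes. Of 30 acinar enzymes 27 did not pass in the authors' deposited table. Their list median was -0.0097 relative to the median gene (list adjusted p 0.647).

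Alcohol versus Normal crosses the same split. Kras averaged 0.794 RPKM in Alcohol and 0.283 in Normal. The largest rises were stomach genes, among them Pgc, which encodes a pepsinogen, Atp4a, the acid pump, and the mucus genes Muc5ac, Mucl3, Gkn1, Gkn2, Tff1 and Psca, with Sprr2a2 and Gsta1. For each of them 1 Alcohol library held at least 80% of the group's sum. Gkn3, Ctse, Agr2 and Gcnt3 rose too, and for them the table does not place the highest library in Alcohol. Duct genes rose, with Cldn4 at 4.48 and Muc1 at 1.54 relative to the median gene, and Krt20 and Tspan8 from 0 reads, while Onecut1 fell. The macrophage genes Cd14, Trem2, Mrc1 and Retnla and the matrix genes Loxl1, Bgn, Postn and Col8a1 rose. Of the acinar and secretory genes, Dnase1 rose from near 0 reads, and Xbp1, Spdef and Gata6 passed only on the deposited scale. The largest falls were Amy2a1, Rn7s1, Rn7s2, Rn7sk, Rpph1, Rmrp, Mir6236, Snora73a, Rnu3b2 and Xist. There were 12712 genes passing in the authors' deposited table, 10585 higher and 2127 lower, and Kras had a log2 ratio of 1.49 with an FDR of 0.0133. About the median gene (1.11) 2106 rose and 3687 fell.

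**Figure D3:**
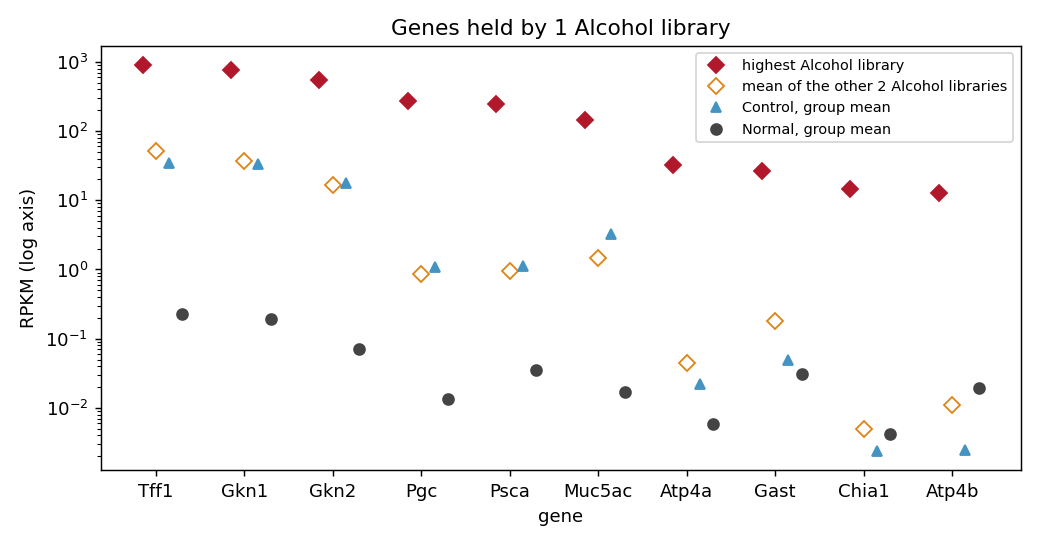
Highest Alcohol library, mean of the other Alcohol libraries and authors' means of Control and Normal (RPKM, log axis) for 10 genes that 1 Alcohol library held. Atp4a reached 32.5 RPKM in the highest library, where the others averaged 0.045.

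Of the lists, 22 of 27 gastric, 25 of 26 duct, 23 of 24 macrophage and 31 of 32 matrix genes passed as higher in the authors' deposited table. Adjusted over the list alone these were 22, 25, 24 and 31, and 17, 18, 19 and 20 rose about the median gene. In that order, the list adjusted p values were 5.03e-07, 5.03e-07, 0.000439 and 0.000295. Of 19 acinar and secretory genes 4 passed as higher, 3 adjusted over the list alone, and 1 rose and 1 fell about the median gene (list adjusted p 0.690 on the deposited scale).

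All versus Control and All versus Alcohol compare groups of the same genotype across the split. Kras averaged 1.42 RPKM in All. Acinar genes fell in both, led by Pla2g1b, Prss3 and Try5, with Rnase1 against Control and Try10 against Alcohol. Pla2g1b averaged 1.19 RPKM in All, 110 in Control and 42.8 in Alcohol. The tuft cell gene Dclk1 rose in both, while Ptgs1, Alox5, Siglecf and Pou2f3 did not pass about the median gene where they were named by the rule. The T cell genes Il2ra, Cd3e, Gzma and Nkg7 passed as higher than Control on the deposited scale and not about the median gene. The largest rises were again Rn7s1, Rn7s2, Rn7sk, Rpph1, Rmrp, Mir6236, Snora73a, Xist and Amy2a1, with Scarna2 against Control and Snora73b against Alcohol. The pseudogenes Rps23-ps2, Tpt1-ps5, Rpl31-ps11, Rpl21-ps15, Rpl28-ps3, Rpl5-ps2, Rps13-ps1, Rps18-ps3 and Rps2-ps10, and Rpl5-ps1 against Alcohol, made up 9 of the 10 largest falls against Control and 10 against Alcohol, and their values are uncertain. Against Control, 18298 genes passed in the authors' deposited table, 17377 higher and 921 lower, and against Alcohol 12359, 11171 higher and 1188 lower. About the median gene (2.06 and 0.95) 3131 rose and 4203 fell against Control, and 3534 and 2518 against Alcohol.

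Kras had a log2 ratio of 1.81 against Control (FDR 0.000275) and 0.84 against Alcohol (FDR 0.0286) in the authors' deposited table, and lay below the median gene in both (-0.24 and -0.11). Of 30 acinar enzymes 28 were lower against Control and 27 against Alcohol, the same adjusted over the list alone, and 1, Amy2a1, was higher in each (list adjusted p 2.82e-25 and 3.48e-13). Of 12 tuft cell genes 12 were higher against Control and 8 against Alcohol in the authors' deposited table, with 12 and 9 adjusted over the list alone, and of 25 T and NK cell genes 24 were higher against Control, also adjusted over the list alone, and 1 against Alcohol. Only 1 tuft cell gene rose about the median gene in each comparison, and none of the 20 T and NK cell genes so tested rose against Control. Neither list passed (list adjusted p 0.968 and 0.976 for tuft cells, 0.414 for T cells).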

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

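All tests in this part were chosen after the results were seen, as was the minimum of 100 RPKM for the genes listed first. The column of the highest library, which is no part of the comparisons of group means, showed 9 protein-coding genes above that minimum with at least 80% of a group's sum in 1 library. In Alcohol these were Tff1 at 896 RPKM, Gkn1 at 759, Gkn2 at 545, Pgc at 269, Psca at 250, Muc5ac at 145 and Mucl3 at 136. In All they were the inflammatory genes Saa3 at 161 RPKM and S100a8 at 113. Each lay above the authors' means of Normal and Control. The other Alcohol libraries averaged 51.2 RPKM for Tff1, 37.0 for Gkn1, 0.855 for Pgc and 1.45 for Muc5ac.

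For 7 of 27 genes of the fixed gastric list, 1 Alcohol library held at least 80% of the group's sum. For these, stomach tissue in a sample is a candidate explanation, since pancreas does not hold parietal cells. Of 10 parietal genes 4 had at least 80% of the Alcohol sum in 1 library (6 without the minimum of 0.1 RPKM), with Atp4a at 32.5 RPKM, Atp4b at 12.7 and Cblif at 3.48, and so had 6 of 10 genes of chief and endocrine cells, including Gast at 26.1. Gastric-type metaplasia in 1 animal, the biological alternative, would need duct markers to follow. Of 26 duct markers 1 did, but this count cannot decide. The rule places a maximum in Alcohol only where it exceeds the sum of every other group, and duct genes were high in All. Cldn4 averaged 18.7 RPKM in the 6 All libraries and 16.6 in the 3 Alcohol libraries, so the rule could not count it. Metaplasia stays open. The table does not show whether the same library held each gene, and no count without it could be made.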

How the results depend on the processing

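The mean of at least 1 RPKM, the median-gene test over all genes, the list tests on ranks and the correlation of 0.05 were chosen after the data were seen. Counts below are in the order All versus Normal, Alcohol versus Control, Control versus Normal, Alcohol versus Normal, All versus Control, All versus Alcohol, and the counts of the authors' deposited table were 17691, 17, 5653, 12712, 18298 and 12359 genes. Where no reason is given, the cause was not tested.

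Median-ratio rescaling gave 5454, 25, 5249, 5793, 7334 and 6052 genes, because it removes the shift of the median gene, and the share of higher calls went from 97.1% to 50.2%, 88.2% to 0%, 53.8% to 45.1%, 83.3% to 36.4%, 94.97% to 42.7% and 90.4% to 58.4%. Over all genes it gave 6015, 53, 5164, 5961, 7847 and 6417. Scaling on reads outside the acinar enzymes gave 15868 genes (95.6% higher), 8 (0%), 16211 (93.0%), 17082 (91.6%), 8299 (28.5%) and 8395 (26.8%). The structural RNAs take part in that scaling, so it follows the split between groups. Reads outside both the acinar enzymes and the structural RNAs had log2 ratios, at equal depth, of 1.82, 0.77, 0.38, 1.15, 1.44 and 0.67. The median gene lay at 2.01, 0.93, 0.14, 1.11, 2.06 and 0.95. The shift of the median gene therefore had the same sign as the shift of these reads in each comparison. In All versus Control it was clearly larger. Gene counts on a scaling by these reads are not given. Fewer genes were tested at a mean of at least 10 RPKM (540, 1, 193, 421, 550 and 382) and at least 1 RPKM (5530, 2, 1549, 3732, 5454 and 3762). Against an absolute log2 difference of 1 the counts were 13344, 0, 2031, 4240, 12481 and 4069. For Alcohol versus Control this count of 0 by the recovered limma-type test stands beside 9451 genes with an unadjusted p under 0.05 in the authors' deposited table.

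Of the 45 lists, 22, 14, 16, 11, 9 and 10 passed the main list test. About the median gene these were 30, 16, 16, 19, 9 and 7, on ranks 26, 14, 26, 18, 20 and 22, and with a correlation of 0.05 they were 20, 8, 10, 5, 7 and 3, as a larger correlation widens the error.

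Of the named genes, 219 values kept their direction and side of the threshold under median-ratio rescaling, 30 kept their direction and no longer passed, and 16 changed sign and did not pass either. Under the scaling outside the acinar enzymes these were 243, 17 and 4 that changed sign, and 1 newly passed. In All versus Normal, median-ratio rescaling, by subtracting 2.01, turned Gzmb (0 reads in Normal) to -0.41, Il2ra to -0.32, Jchain to -0.00044, Canx to -0.29, Ppp1r15a to -0.55, Got2 to -0.12, Slc1a5 to -0.57, Rpl14 to -0.59, Rps19 to -0.48, Rps5 to -0.57, Rpl18 to -0.48 and Tyms to -0.039. Gata6 in Alcohol versus Normal turned to -0.20. Canx in Alcohol versus Control, which did not pass as deposited, turned to -0.23 and, with the scaling outside the acinar enzymes, to -0.081. Kras turned to -0.24 in All versus Control and -0.11 in All versus Alcohol, and to -0.58 and -0.77 with the scaling outside the acinar enzymes, which turned Ptgs1 in All versus Alcohol to -0.10.

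No paired analysis was possible because the table holds group means and no value per library. For the same reason leaving out each replicate, other splits of the samples, another pseudocount, a test without trend, fry and an estimated correlation were not run. Depth limits the genes with fewer than 1 read per library, 30.1% in Normal.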

Other observations

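The tests of explanations in this part, the list tests on ranks, with a correlation of 0.05 and without Egr1 and Fos, and the counts of genes held by 1 library were chosen after the results were seen. Structural RNAs were high in Normal and All and low in Control and Alcohol. Kras overexpression as the cause is argued against by All versus Normal, which differ in genotype, where the median log2 ratio of the 154 structural RNAs was 0.82, against -4.92 in Control versus Normal. Libraries prepared with and without poly(A) selection remain a candidate explanation, since histone genes, whose messages lack a poly(A) tail, had a median of -4.32 relative to the median gene in Control versus Normal. The labels name 1 kit for all libraries. All 6 sex-linked genes passed in the 4 comparisons across the split, with Xist high in Normal and All and Ddx3y high in Control and Alcohol, the pattern of females in the former and males in the latter. Sex follows the same split as the structural RNAs, so no comparison here separates sex from library preparation. The size of the difference argues against sex alone as the cause for these RNAs, which serve protein export and RNA processing in either sex. Of the 154, 145 passed as lower in Control than in Normal and 0 as higher. Their share of reads on listed genes was 0.614% in Control and 52.7% in Normal. Other differences across the split may still follow sex.

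Immediate early genes were lower in Alcohol than in Control, 13 of 13 below the median gene with a median of -2.79. Control was the group that lay furthest from Normal, although comparisons with Normal cross the split. Relative to the median gene, the immediate early and heat shock list lay at 3.05 in Control versus Normal, where 18 of 18 rose. In Alcohol versus Normal it lay at 0.81, and 1 rose. Egr1 averaged 2.12 RPKM in Normal, 22.2 in All, 2.99 in Alcohol and 82.1 in Control. Handling of the tissue before freezing stays open, since the 5 heat shock genes, with a median of -2.12 (from -4.18 to -1.38), belong to the list that showed the pattern and decide nothing. Another time of day at collection stays open too. The 9 clock output genes and 5 clock genes of the opposite phase lay apart by 1.45 (medians 0.58 and -0.86). Both sets were written after the clock pattern had been noticed, and no value ties them to the immediate early genes, so they decide nothing. The fixed clock list did not pass (list adjusted p 0.710, and 0.472 about the median gene). Less activity of the Kras and ERK pathway in Alcohol could not be decided, since 24 other RAS and ERK genes had a median of -0.10, with 14 below the median gene. The fixed list of 26 RAS and ERK genes passed toward lower t values (list adjusted p 0.000672, 0.00372 about the median gene, 0.0505 on ranks and 0.0214 with a correlation of 0.05). Without its immediate early members Egr1 and Fos it did not, with unadjusted p values of 0.123, 0.225, 0.0654 and 0.236 in that order. An effect of alcohol itself stays open as well, since no value here separates it from handling or time of day.

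In the column of the highest library, 1 All library held Scgb1a1 at 12.6 RPKM and Sftpc at 10.9, genes of airway and lung epithelium, with at least 80% of the group's sum, and this held for 4 of 9 lung genes and 7 of 15 neutrophil genes. Among genes with a group mean of at least 1 RPKM whose highest library can lie in only 1 group, 1 library held at least 80% of the sum for 32 of 160 genes in Normal, 0 of 7 in Control, 44 of 170 in Alcohol and 20 of 2930 in All.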
